A study of Mus musculus with 18 samples.

How the data were processed

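The measurements came from 18 two-channel cDNA arrays of mouse kidney, 2 for each of 9 combinations of condition (normoxia, constant hypoxia, intermittent hypoxia) and duration (1, 2 and 4 weeks). Per the labels' protocols, total RNA was extracted in Trizol, 60 ug per channel was reverse transcribed with direct incorporation of Cy5 for the animal labelled male and Cy3 for the animal labelled female, and each array joined animals of one condition. The authors deposited 1 log2 ratio per probe and array. Background correction, spot filtering, normalization and the direction of the ratio are not given in the sources used here. The log base was read from the values: 2 raised to a deposited value equalled a ratio of whole numbers with a denominator up to 600, within a relative tolerance of 3e-09, for 25.3% to 78.5% of 1500 sampled values per array, against at most 0.3% for base e and 0.7% for base 10. The share was lower on the constant hypoxia arrays (25.3% to 46.3%) than on the normoxia (68.2% to 77.9%) and intermittent hypoxia arrays (69.9% to 78.5%). Only ratios were used, so neither the intensity nor the background behind a value is known here.

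Arrays were grouped by their titles. On 2 arrays another label disagreed with the title: the female channel of intermittent hypoxia 2 weeks A is named as a 1-week animal, and a treatment text of constant hypoxia 4 weeks A gives 2 weeks. The arrays of a group were hybridised with different animals per the labels. The letters A and B named arrays and did not pair them across groups.

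Of 16128 probes, 9604 had 1 gene symbol in the platform annotation, 213 had several and 6311 had none, and 1105 had no value on any array. A probe was kept with a value on at least 15 of the 18 arrays and on at least 1 array of every group, which left 6518 probes (40.4%). Probes of the same single symbol were averaged over those with a value on an array. The difference found for a gene can therefore lie outside those of its probes. Probes with no symbol or several stayed separate, which gave 5751 features in all. Different probes of a gene often disagreed: for the 642 genes with several probes the median correlation between probes over arrays was 0.14, and it was below 0 for 33.2% of these genes. No genome build is named with the values, so no coordinates are given.

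The plan fixed before the data were examined used the values as deposited. Because the medians of the constant hypoxia arrays lay as far from 0 as -1.17, each array was instead centred on its median over the features tested, a setting that had been listed as an alternative. That change was made after seeing the files, and counts on the values as deposited stand beside each comparison for which they differ. Centring removes any shift common to all transcripts of an array, so differences are relative to the median feature.

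Ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit with 9 group means, eBayes without trend or robust options, prior degrees of freedom 5.55), and p values were adjusted by Benjamini-Hochberg over all 5751 features with a threshold of 0.05. Contrasts were the mean ratio of each condition against 0, differences between conditions averaged over durations and within each duration, 4 weeks minus 1 week in each condition, and the differences of that change between each hypoxia regime and normoxia. All p values are two-sided and adjusted p values of features and lists are limma's. Gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, which held for 17 lists. The lists tested were HIF targets, glycolysis, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation and peroxisome, endothelium, extracellular matrix, proliferation, erythroid cells, immune cells, antioxidant genes, chaperones, kidney injury, ribosomal proteins, splicing, proteasome and ubiquitin, and translation factors. Lists with fewer measured members (sex-linked and sex-biased genes, nephron segments, podocytes, progenitors, renin-angiotensin genes and neighbouring tissues) were not tested as lists. No list call on the median-centred values held with the estimated correlation, which was the mean residual correlation between members. Fry, which asks whether the members of a list move one way on balance, was run on lists with enough genes measured on all 18 arrays.

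Named genes followed a rule fixed before the data were examined. For the normoxia ratio, the condition differences and maturation in normoxia, up to 10 passing genes in each direction with the same sign at every duration were named, filled to 5 by smallest p. For the other comparisons 3 genes in each direction by smallest p were named, with passing genes of the sex and HIF lists and 2 to 4 examples of each list that passed. One gene that met the rule for the normoxia ratio is not reported. Spreads of arrays and relations between measures were tested by permutation in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

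The fit was tested on simulated data with the real pattern of missing values. Errors were drawn independently for each feature and array. The simulation thus held neither a trend of single arrays along the probe numbers nor correlation between members of a list. The rates below apply to such errors and may not hold for the real ones. For constant hypoxia minus normoxia over 5751 features, 91% of 100 features changed by log2 1 and 100% of 100 changed by log2 2 were called, with 0.23% of unchanged features called. For 4 weeks minus 1 week in normoxia over 5751 features, 31% and 96% were called, with 0.2% of unchanged features. A shift of 0.25 in all 18 tricarboxylic acid cycle genes was found in the first of these contrasts and missed in the second.

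Alternatives fixed before the data were examined were the array letter as a block, an additive model, only the arrays compared, other scalings (as deposited, scaled to 1 median absolute deviation, quantile), other filters on missing values, each probe on its own, robust moderation, array weights, unmoderated tests, a threshold of 0.10, and leaving out each array. Chosen after seeing the data were the removal on each array of a running median over 51 consecutive probe numbers, the removal of medians of larger blocks of probe numbers, and leaving out constant hypoxia 4 weeks A and intermittent hypoxia 2 weeks B together. The trend was looked for because residuals of neighbouring probe numbers correlated (mean r over arrays 0.45 at a distance of 1 and 0.46 at 3), against a median of -0.02 over 20 large distances.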

Results

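Kidney transcripts of CD1 mice, an outbred laboratory stock, were measured on 18 two-channel cDNA arrays. From postnatal day 2 the pups lived for 1, 2 or 4 weeks in room air (normoxia), in air held at 11% oxygen (constant hypoxia), or in air switched between 21% and 11% oxygen every 4 min (intermittent hypoxia). Each of the 9 combinations of condition and duration had 2 arrays, named A and B here. Per the labels, every array carried kidney cDNA of a male in Cy5 and of a female in Cy3, both from the same condition, and the dyes were not swapped. The measured value was the log2 ratio of the channels of one array. A response to oxygen that was equal in the paired animals cancels in this ratio, so the comparisons between conditions or ages show only where the ratio itself changed. Which channel stands in the numerator is not given in the sources used here. Positive and negative below are the signs of the deposited value relative to the median of its array, and they carry no statement about sex.

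A value was present for 41.0% to 67.9% of all probes on the normoxia arrays, 42.9% to 65.7% on the intermittent hypoxia arrays and 81.8% to 88.8% on the constant hypoxia arrays. The median deposited log2 ratio lay between -0.07 and 0.09 on the normoxia arrays, between -0.03 and 0.03 on the intermittent hypoxia arrays and between -1.17 and -0.15 on the constant hypoxia arrays. The constant hypoxia values had thus been deposited on another footing, and each array was centred on its median before any comparison. Centring removes a shift shared by all features of an array, but no difference in background correction or spot filtering. All constant hypoxia arrays and no others differed in this way. In their ratios and comparisons, constant hypoxia therefore cannot be told apart from this footing. The tests covered 5751 features, of which 4109 were genes and 1642 were probes without a single gene symbol. The number of arrays limits the precision. The median standard error was 0.12 log2 units for a condition mean, 0.17 for constant hypoxia minus normoxia and 0.295 for a difference between 2 groups of 2 arrays, here 4 weeks minus 1 week in normoxia.

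**Figure D1:**
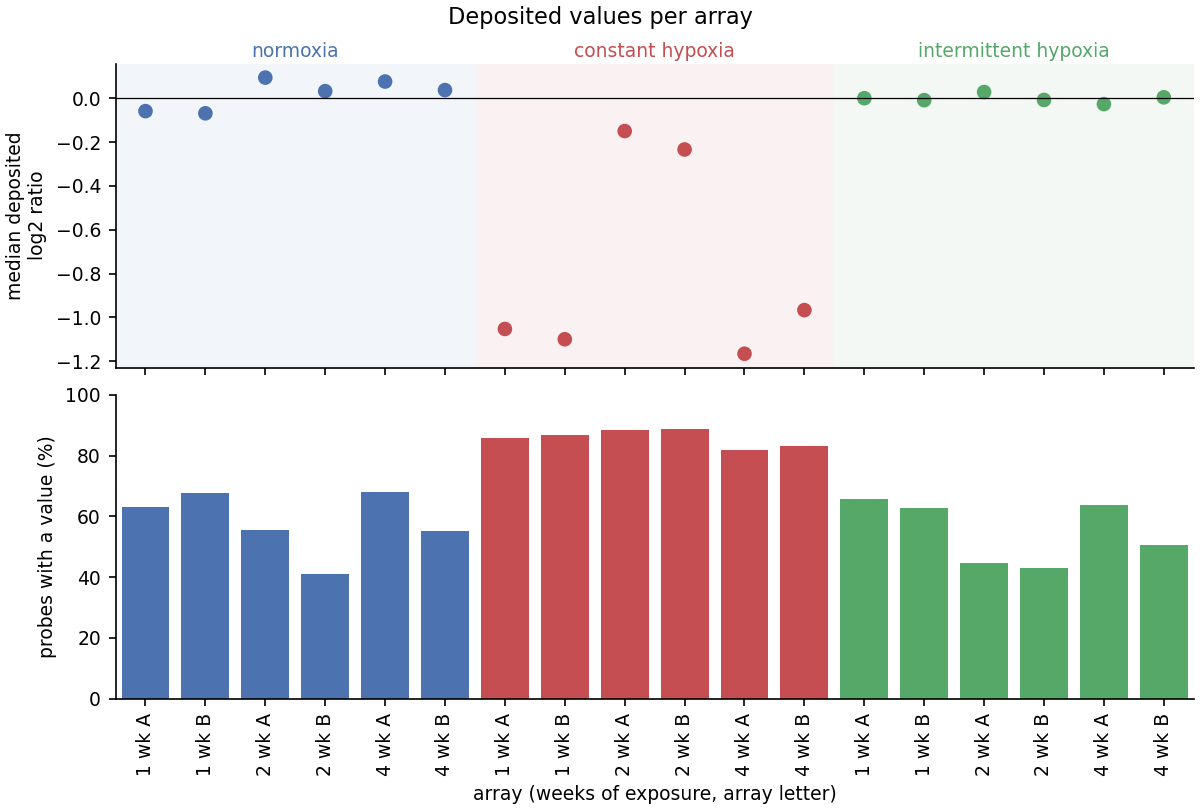
Median deposited log2 ratio (upper panel) and percentage of probes with a value (lower panel) on each of the 18 arrays, coloured by condition. The 6 constant hypoxia arrays had medians of -0.15 to -1.17 and values for at least 81.8% of the probes, against at most 67.9% on the other arrays.

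Sex-linked transcripts were examined first, because every array was labelled as a male against a female. Eif2s3y, a Y-linked gene for a translation initiation factor subunit, should have 1 sign on all arrays under these labels. Its ratio was above 1 on 3 arrays, reaching 1.64 on normoxia 4 weeks B, below -1 on 4 arrays, reaching -2.16 on intermittent hypoxia 1 week A, and within 1 of 0 on the remaining 11. A probe annotated to both Xist and Tsix, overlapping transcripts of the X-inactivation centre, exceeded 1 log2 unit in size on 10 of the 16 arrays where it had a value, with 6 positive and 4 negative ratios. Its sign was opposite to that of Eif2s3y on 9 of these 10 arrays (two-sided exact binomial p = 0.0215), the exception being intermittent hypoxia 1 week B. Chosen probes of other genes were compared with it. Those of Sfpq (r = 0.97 over 15 arrays) and Kif1b (r = 0.88 over 13 arrays) lay close to it in probe number. That of Nfix (r = 0.94 over 14 arrays) lay far from it. Each had the same sign as the Xist and Tsix probe on 9 of 9 arrays with large ratios. Probes near that of Eif2s3y were not examined in this way. The spot of the Xist and Tsix probe therefore cannot be taken as a clean reading of these transcripts. Of the probes annotated to Xist alone, one stayed between -0.41 and 0.33 on 9 of the 10 arrays and the other was negative on all 5 of them where it had a value (-2.68 to -0.13), so neither followed it. Kdm5c, an X-linked histone demethylase gene that escapes inactivation, was negative on all 18 arrays (-0.71 to -0.01).

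Androgen-dependent kidney genes gave a second reading. The mean ratio of Gusb, Nudt19, Odc1 and Timd2, of which Odc1 encodes ornithine decarboxylase and Gusb beta-glucuronidase, was taken over the genes with a value on each of the 6 arrays of 4 weeks, all 4 except on constant hypoxia A, where Nudt19 had none. It was 0.01 and 1.56 on normoxia A and B, 1.11 and 0.91 on constant hypoxia A and B, and 0.01 and -0.97 on intermittent hypoxia A and B. Over these 6 arrays it rose with the Eif2s3y ratio (Pearson r = 0.98, exact permutation p = 0.00278, adjusted p = 0.0222 over 8 relations computed; Spearman correlation 0.94, exact permutation p = 0.0167; r = 0.97 without the 2 arrays farthest from the median). Gusb alone was positive on all 6 of these arrays. It was 0.13 on constant hypoxia A and 0.77 on intermittent hypoxia B, where Eif2s3y was 1.13 and -1.63. Slc22a7, the female-biased gene among those fixed beforehand, did not run against Eif2s3y on these arrays, with 0.69 on normoxia B, 0.66 on constant hypoxia A and -0.31 on intermittent hypoxia B. Over all 18 arrays Kdm5c was not shown to follow Eif2s3y (r = -0.16, permutation p = 0.53), and the mean of Kdm5c, Ddx3x and Kdm6a had r = -0.51 with it (permutation p = 0.0288, adjusted p = 0.115). The correlation of each array with the mean of the others, across features, lay between 0.10 and 0.72. Eif2s3y and the mean of the androgen-dependent genes did not keep 1 sign, while Kdm5c did. The channels are therefore called labelled male and labelled female, and no ratio is read as a difference between the sexes.

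**Figure D2:**
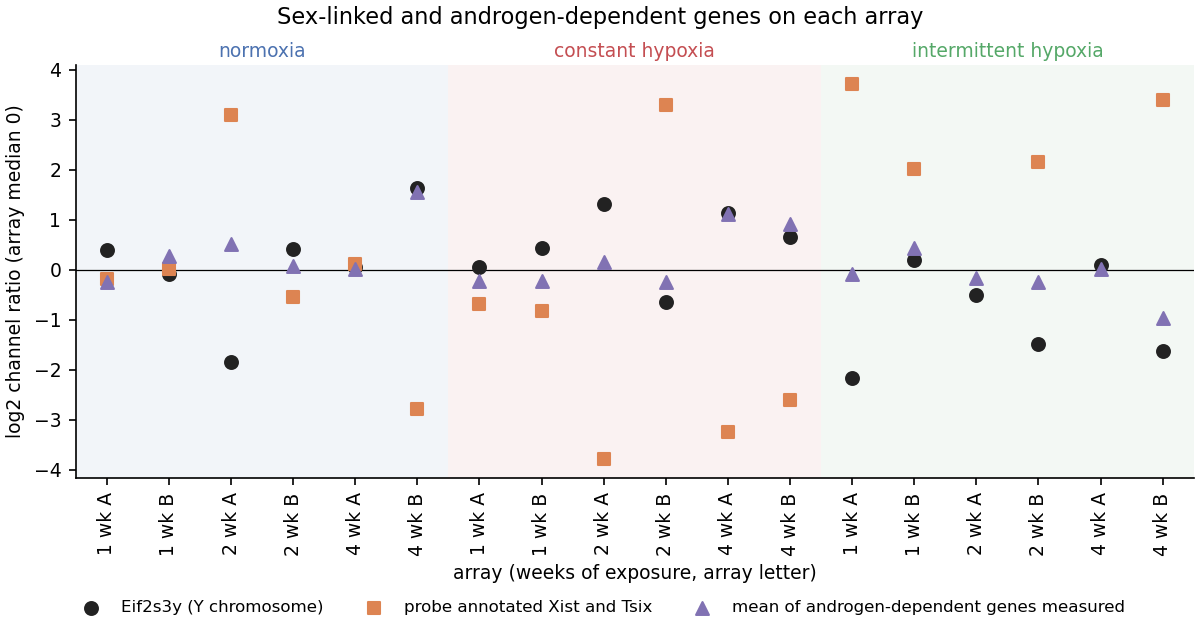
Log2 channel ratio, centred on the array median, of Eif2s3y (circles), the probe annotated Xist and Tsix (squares) and the mean of the androgen-dependent genes with a value, up to 4 (triangles), on each array, grouped by condition. Eif2s3y and the Xist and Tsix probe had opposite signs on 9 of the 10 arrays where the latter exceeded 1 log2 unit in size.

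In normoxia the negative mean ratios that passed included those of Gpx3 and Sgk1. Gpx3, a secreted glutathione peroxidase made in the kidney, had a mean log2 ratio of -0.85 (SE 0.13, adjusted p = 0.0132, 6 arrays), and Sgk1, a kinase that regulates epithelial sodium transport, of -0.79 (SE 0.13, adjusted p = 0.0132, 6 arrays). Agt, which encodes angiotensinogen, had -0.64, and Mgp, an inhibitor of calcification, had -0.78. Sf3b1, a splicing factor, had -0.93, Fcgbp -0.86, Abhd4 -0.85, Elp5 -0.73, the chemokine scavenging receptor Ackr3 -0.67, and the ETS transcription factor Etv5 -0.66. Among the positive genes were Gpam, the mitochondrial acyltransferase that begins triglyceride synthesis (0.86, SE 0.19, adjusted p = 0.0321), Ggps1, which makes geranylgeranyl diphosphate (0.73), Rbpms2 (0.71), Haus6 (0.71), Agtrap, a binding partner of the angiotensin II type 1 receptor (0.69), Mllt1 (0.65), Ddx31 (0.64), Cdcp1 (0.64) and Rccd1 (0.64). By the naming rule each of these genes kept its sign at 1, 2 and 4 weeks. Sizes varied for some, with 1.57, 0.39 and 0.10 for Agtrap and -0.34, -1.55 and -0.08 for Etv5. Gpam, Rbpms2, Agtrap, Ddx31, Cdcp1, Ackr3 and Etv5 had values on 5 of the 6 normoxia arrays, and Ggps1 on 4. At least 1 duration of each thus rested on a single array, among them 1 week for Agtrap and 2 weeks for Etv5.

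In all, 203 features passed in normoxia, 114 positive and 89 negative, by limma's moderated test against a ratio of 0, and 1246 had an unadjusted p under 0.05. On the values as deposited 149 passed, 79 positive and 70 negative. None of the 17 gene lists tested passed in this contrast, the smallest adjusted p being 0.35. With the running median of probe numbers removed, the tricarboxylic acid cycle passed (2 of 17 positive, adjusted p = 0.0123, and adjusted p = 0.559 with an estimated correlation). Without normoxia 4 weeks B 13 features passed, and without either constant hypoxia 4 weeks array 453. With constant hypoxia 4 weeks A and intermittent hypoxia 2 weeks B both left out, a setting chosen after seeing the data, 725 passed. After removal of a trend along the probe numbers 76 passed with a running median, 30 of them among the 203, whose median size went from 0.50 to 0.24, and 390 passed with block medians. Of the genes named above, Haus6, Rccd1, Sf3b1, Fcgbp, Sgk1 and Etv5 stayed past the threshold with the running median removed. The dyes were not swapped, so a gene-specific dye effect is part of every ratio.

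Under constant hypoxia the negative ratios with the smallest p belonged to Dynlt1b, a dynein light chain (-1.74, SE 0.22, adjusted p = 0.00242), the interferon-induced membrane protein gene Ifitm3 (-1.48, SE 0.17, adjusted p = 0.0021) and Aldh3a2, a fatty aldehyde dehydrogenase (-1.01, SE 0.11, adjusted p = 0.0021). Ifitm3 and Aldh3a2 had values on 5 of the 6 arrays, with 1 array alone at 4 weeks. Rap1b, a small GTPase (0.62), the metalloprotease gene Adam19 (0.47) and the proteasome subunit gene Psmd1 (0.53) were positive. Of the genes fixed for sex or hypoxia, Kdm5c (-0.37, adjusted p = 0.0229), the organic anion transporter gene Slc22a7 (0.36, adjusted p = 0.0252) and the growth factor binding protein gene Igfbp3 (-0.39, adjusted p = 0.0257) passed. A total of 1050 features passed, 288 positive and 762 negative, with 2055 at an unadjusted p under 0.05, while a fit of the constant hypoxia arrays alone passed 0. No gene list passed, the smallest adjusted p being 0.136 for the ribosomal proteins. With the running median of probe numbers removed, ribosomal proteins (14 of 67 positive, adjusted p = 0.000134), oxidative phosphorylation (9 of 44, adjusted p = 0.000483) and kidney injury genes (1 of 5, adjusted p = 0.0188) passed. With an estimated correlation their adjusted p values were 0.524, 0.839 and 0.408. The calls of single features depended on the processing: on the values as deposited 5687 features passed, all negative, which turned Rap1b to -0.16, Adam19 to -0.31, Psmd1 to -0.25 and Slc22a7 to -0.43. After removal of the trend along the probe numbers 2 features passed with a running median, with Aldh3a2 at 0.12, and 561 with block medians, and without constant hypoxia 1 week B 6 passed.

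Under intermittent hypoxia Arrb2, which encodes beta-arrestin 2 (0.96, SE 0.12, adjusted p = 0.00468), Tubb6, a beta-tubulin (0.96, SE 0.12, adjusted p = 0.00468) and Htatsf1, an RNA-binding protein gene (1.04, SE 0.14, adjusted p = 0.00531) were positive. Arrb2, Tubb6 and Htatsf1 had values on 5, 4 and 4 of the 6 arrays (SD 0.92, 0.85 and 0.61). At least 1 duration of each thus rested on a single array. The choline transporter-like gene Slc44a2 (-0.65, 5 arrays), Gpx3 (-0.78) and Fcgbp (-0.90) were negative. In this condition 333 features passed, 246 positive and 87 negative, with 1417 at an unadjusted p under 0.05. On the values as deposited 234 passed, 137 positive and 97 negative. No gene list passed, the smallest adjusted p being 0.0759 for the ribosomal proteins. With the running median of probe numbers removed, chaperones (3 of 19 positive, adjusted p = 0.0208) and the tricarboxylic acid cycle (1 of 17 positive, adjusted p = 0.0325) passed. Each had an adjusted p of 0.779 with an estimated correlation. Without intermittent hypoxia 1 week B 43 features passed, and without intermittent hypoxia 2 weeks A 899 passed. After removal of the trend along the probe numbers 101 passed with a running median, 45 of them among the 333, whose median size went from 0.49 to 0.20, and 703 passed with block medians. Of the genes named, Slc44a2 and Gpx3 lost their calls with the running median removed. A total of 47 features passed in all 3 conditions, each with the same sign in all 3. Across features, which are not independent replicates, mean ratios of normoxia correlated with those of constant hypoxia (r = 0.66) and of intermittent hypoxia (r = 0.66), and those of both hypoxia regimes with each other (r = 0.56).

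**Figure D3:**
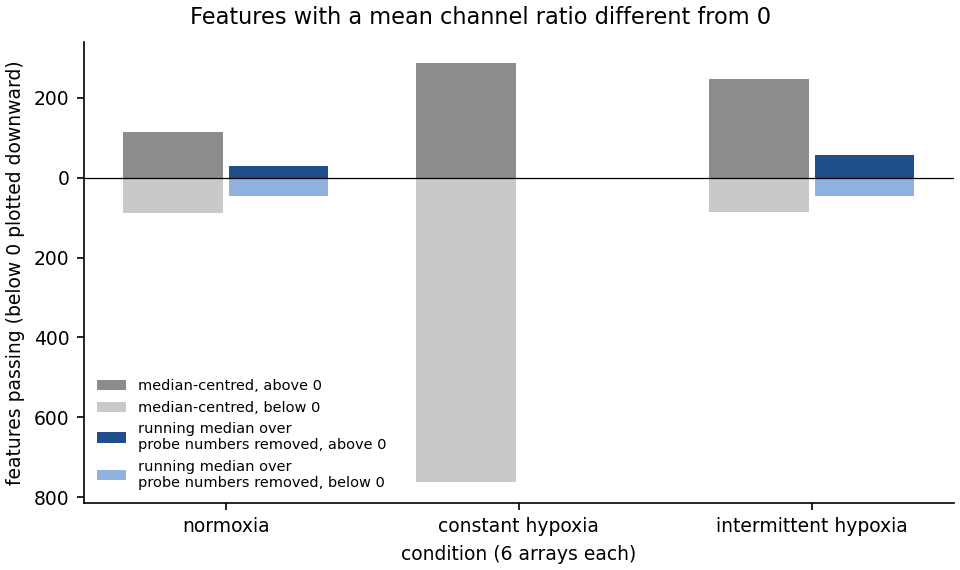
Number of features whose mean log2 channel ratio differed from 0 in each condition (6 arrays each), above 0 plotted upward and below 0 plotted downward, for median-centred values (grey) and after removal of a running median over probe numbers (blue). The counts went from 203 to 76 in normoxia, from 1050 to 2 in constant hypoxia and from 333 to 101 in intermittent hypoxia.

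Constant hypoxia was compared with normoxia over the 3 durations to ask whether sustained low oxygen altered the ratio. The other footing of the deposited constant hypoxia values is part of this comparison. The list of tricarboxylic acid cycle enzymes shifted upward, with 13 of 18 genes positive, a median difference of 0.17 and an adjusted p of 0.013 from limma's camera test. With an estimated correlation between its genes the adjusted p was 0.415. The call was lost on leaving out any of 5 of the 18 arrays, with a median of 0.06 without normoxia 2 weeks B and an adjusted p of up to 0.154. The members with the smallest p were Sdhd (0.56, SE 0.16, adjusted p = 0.647) and Sdha (-0.52, SE 0.25), both subunits of succinate dehydrogenase, Pdhb (0.42), a pyruvate dehydrogenase subunit, and Idh3b (0.42), an isocitrate dehydrogenase subunit. The 2 probes of Idh3b gave 0.17 and 0.38, both below its averaged value. No member passed among all features, and 1 passed when adjusted over the list alone. Targets of the hypoxia-inducible factor, HIF, had 11 of 15 differences positive, with a median of 0.11 that did not pass (adjusted p = 0.0786). Glycolysis had 6 of 7 positive (median 0.21, adjusted p = 0.0786). Erythroid markers had 1 of 5 positive with a median of -0.45 (adjusted p = 0.0869), and their mean ratio on constant hypoxia 4 weeks A was -1.67.

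No single feature passed in constant hypoxia minus normoxia by limma, with 433 at an unadjusted p under 0.05, and none passed by the unmoderated test with Benjamini-Hochberg adjustment. The smallest p values belonged, with positive differences, to Ptgr2 (0.49), Sdhd, Etv5 (0.57), Aar2 (0.42) and Wdr43 (0.44), and with negative differences to Ifitm3 (-1.26, SE 0.23, adjusted p = 0.319), Nol7 (-0.66), Micos13 (-0.88), Prkag1 (-0.86) and Ube2g1 (-0.53). On the values as deposited the median feature was shifted by -0.81 and 5570 features passed, all negative. All 5 positive genes above, and Pdhb and Idh3b, were then negative, between -0.21 and -0.35. Within single durations, 0 features passed at 1 week, with 142 at an unadjusted p under 0.05 and 4466 passing on the values as deposited. At 2 weeks Hdc, the histidine decarboxylase that makes histamine, passed (-5.68, SE 0.77, adjusted p = 0.0369), with ratios of 3.01 and 2.83 on the normoxia arrays and -4.0 and -1.52 on the constant hypoxia arrays. At 4 weeks Aldh3a2 (-2.22, adjusted p = 0.0216) and Ifitm3 (-2.90, adjusted p = 0.0481) passed, and 5247 features passed on the values as deposited, all negative. Aldh3a2 and Ifitm3 had values on 5 of the 6 constant hypoxia arrays, with 1 array alone at 4 weeks. With the trend along the probe numbers removed Hdc stayed past the threshold (-4.86, adjusted p = 0.0093), while Aldh3a2 stood at 0.03 and Ifitm3 at -0.80. Tricarboxylic acid cycle enzymes passed at 1 week alone (14 of 18 positive, median 0.24, adjusted p = 0.00508, and adjusted p = 0.633 with an estimated correlation), with constant hypoxia B apart (array median 0.26) and A at -0.10, between the normoxia arrays (-0.20 and -0.05), and no list passed at 2 or 4 weeks. These 3 genes were named for single durations after their values had been seen. Without constant hypoxia 4 weeks B, 567 features passed in the comparison over all durations, with constant hypoxia 4 weeks A then alone in its group.

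Intermittent hypoxia was compared with normoxia in the same way. The positive differences with the smallest p were those of Cops8, a COP9 signalosome subunit (0.76, SE 0.15, adjusted p = 0.898), Epb41l1 (0.78), Lin54 (0.70), the lysyl-tRNA synthetase gene Kars (0.58) and Abr (0.48). The negative ones were those of Cep170b (-0.65), Cox7a2, a cytochrome c oxidase subunit (-0.46), Ifi27 (-0.56), Trim37 (-0.42) and the translation termination factor gene Etf1 (-0.45). None of these 10 genes passed. Each of the 2 probes of Trim37 gave -0.34, smaller in size than its averaged value. HIF targets had 10 of 15 differences positive (median 0.10, adjusted p = 0.582), and all 5 kidney injury genes were positive with a median of 0.18 that did not pass (adjusted p = 0.434). No list passed. By limma 0 features passed, with 237 at an unadjusted p under 0.05, and 0 passed on the values as deposited and by the unmoderated test with adjustment. At 2 weeks alone 5 features passed, all positive, named after their values had been seen: the E-cadherin gene Cdh1 (2.10, SE 0.30, adjusted p = 0.0222), Cops8 (1.80), the zinc transporter gene Slc39a10 (3.24), the kinetochore gene Zwint (1.62) and an unnamed probe (2.37). Cops8 had values on 4 of the 6 intermittent hypoxia arrays, with 1 array alone at 2 weeks. On the values as deposited 2 features passed at 2 weeks. With the trend along the probe numbers removed Cdh1 stood at 0.71 (adjusted p = 0.233), while Cops8 (1.27), Slc39a10 (2.57) and Zwint (1.14) stayed past the threshold. At 1 and at 4 weeks 0 features passed, with 167 and 502 at an unadjusted p under 0.05. Lists passed within single durations in opposite directions, none with an estimated correlation. Ribosomal proteins were higher at 1 week (50 of 67 positive, median 0.13, adjusted p = 0.00345, and adjusted p = 0.489 with an estimated correlation), where normoxia A was lowest (array medians -0.23 and -0.03 in normoxia, 0.06 and 0.00 in intermittent hypoxia), and lower at 2 weeks (16 of 67 positive, median -0.30, adjusted p = 0.000295, and adjusted p = 0.456 with an estimated correlation). Glycolysis was higher at 1 week (6 of 7 positive, median 0.36, adjusted p = 0.0104, and adjusted p = 0.489 with an estimated correlation) and lower at 4 weeks (1 of 7 positive, median -0.32, adjusted p = 0.0177, and adjusted p = 0.23 with an estimated correlation). The tricarboxylic acid cycle was lower at 4 weeks (3 of 18 positive, median -0.32, adjusted p = 0.0177, and adjusted p = 0.23 with an estimated correlation). The array intermittent hypoxia 2 weeks B, which enters the 2-week comparison, had 13.67% of its features beyond 2-fold, against at most 1.02% on the other intermittent hypoxia arrays.

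Between the regimes Arrb2, whose product ends signalling of G-protein-coupled receptors, had a ratio 1.08 higher under intermittent than constant hypoxia (SE 0.16, adjusted p = 0.0467), and an unnamed probe was 1.57 higher (SE 0.21, adjusted p = 0.0467). These were the 2 features that passed by limma, with 654 at an unadjusted p under 0.05. Arrb2 had values on 5 of the 6 intermittent hypoxia arrays (SD 0.92), so 1 duration there rested on a single array. The fits below that left out 1 array could not leave out that one, so they do not test its weight. Tubb6 (0.88, adjusted p = 0.14), Plpp5 (0.85), the inositol trisphosphate receptor gene Itpr2 (0.53) and Ube2g1 (0.61) followed without passing. Slc44a2 (-0.70), Etf1 (-0.55), Dnajc2 (-0.71), Pdia6 (-0.54) and Irgq (-0.84) had the smallest p among the negative differences and did not pass either. No list passed, and tricarboxylic acid cycle enzymes had 6 of 18 genes positive (median -0.06, adjusted p = 0.152). With the running median of probe numbers removed the latter had 4 of 17 positive (median -0.20, adjusted p = 0.00824, and adjusted p = 0.698 with an estimated correlation), and chaperones had 3 of 19 (median -0.14, adjusted p = 0.0362, and adjusted p = 0.698 with an estimated correlation). The Arrb2 call was lost in 15 of 17 fits that left out 1 array (adjusted p up to 0.27, difference 0.99 to 1.16). It was also lost with the array letter as a block, under the additive model and by the unmoderated test with adjustment, each of which passed 0 features, and with a running median of probe numbers removed (0.76, adjusted p = 0.158). It held with medians of larger probe-number blocks removed, where 3 features passed. On the values as deposited 5386 features passed, all positive, and Slc44a2 (0.03), Etf1 (0.19), Dnajc2 (0.03) and Pdia6 (0.23) turned positive.

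Maturation was examined as 4 weeks minus 1 week. In normoxia glycolytic genes shifted upward, with 6 of 7 positive and a median of 0.32 (adjusted p = 0.0277, and adjusted p = 0.436 with an estimated correlation). Pgk1, phosphoglycerate kinase, had 1.05 (SE 0.23, adjusted p = 0.227), Ldhb 0.70, Hk1 0.32 and Ldha 0.33. No member passed among all features, and 1 passed when adjusted over the list alone. Tricarboxylic acid cycle enzymes shifted the same way, with 15 of 18 positive and a median of 0.24 (adjusted p = 0.0309, and adjusted p = 0.436 with an estimated correlation). Among them were Dld (0.74), Pdha1 (0.58), the citrate synthase gene Cs (0.64) and Idh3g (0.56), none of which passed. On leaving out 1 array Idh3g ranged from 0.13 to 0.99, Cs from 0.32 to 0.96 and Pdha1, whose 2 probes gave 0.23 and 0.91, from 0.36 to 0.80. By limma 0 features passed in normoxia, with 491 at an unadjusted p under 0.05, and 0 by the unmoderated test with adjustment and on the values as deposited. The smallest p values after Pgk1 were those of Sec62 (1.16), Entpd4 (0.97), the saposin precursor gene Psap (1.03) and Ccdc91 (0.73), and of Ubap2 (-1.36, SE 0.24, adjusted p = 0.145), the antigen-loading gene Tapbp (-1.28), Efhd2 (-1.0), the desmosomal cadherin gene Dsc2 (-1.21) and Ppp4c (-1.09). The 2 probes of Entpd4 gave 0.8 and 0.79, both below its averaged value. From 1 to 2 weeks and from 2 to 4 weeks 0 features passed, with 412 and 687 at an unadjusted p under 0.05. Ribosomal proteins were higher at 2 weeks than at 1 week (51 of 67 positive, adjusted p = 0.00416, and adjusted p = 0.871 with an estimated correlation) and lower at 4 weeks than at 2 weeks (17 of 67 positive, adjusted p = 0.0331, and adjusted p = 0.523 with an estimated correlation). From 2 to 4 weeks the tricarboxylic acid cycle (15 of 18 positive, adjusted p = 0.00333), glycolysis (6 of 7 positive, adjusted p = 0.00534) and antioxidant genes (12 of 17 positive, adjusted p = 0.0331) were higher, each with an adjusted p of 0.346 with an estimated correlation. Normoxia 2 weeks B stood apart in these lists, with array means of -0.565, -0.547 and -0.441 against -0.048, -0.016 and -0.137 on its partner array. Without normoxia 1 week B the glycolysis list had an adjusted p of 0.088, and without normoxia 1 week A the tricarboxylic acid cycle list had a median of 0.10 and an adjusted p of 0.276.

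Under constant hypoxia no list passed between 1 and 4 weeks. Glycolysis had 5 of 7 genes positive (median 0.38, adjusted p = 0.109). Erythroid markers had 1 of 5 positive with a median of -1.09 (adjusted p = 0.074), and 4 of them passed with negative differences when adjusted over the list alone. With the trend along the probe numbers removed the median was -0.46 (adjusted p = 0.176), and the 4-week arrays differed, with array means of -1.67 on A and -0.50 on B. By limma 0 features passed, with 585 at an unadjusted p under 0.05, and 0 by the unmoderated test with adjustment. The positive differences of smallest p were those of the ubiquitin-conjugating enzyme gene Ube2o (1.38), Chst11 (1.06) and the mitochondrial carrier gene Slc25a39 (1.10), and the negative ones those of Ifitm3 (-2.66), Aldh3a2 (-1.63) and the histone deacetylase gene Hdac2 (-1.98). Ifitm3 and Aldh3a2 had a value on only 1 of the 4-week arrays. With the trend along the probe numbers removed Aldh3a2 stood at 0.39 and Hdac2 at 0.05. The array constant hypoxia 4 weeks A had 16.39% of its features beyond 2-fold, and without its partner array 752 features passed.

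Under intermittent hypoxia glycolytic genes shifted downward between 1 and 4 weeks, with 0 of 7 positive and a median of -0.22 (adjusted p = 0.0291, and adjusted p = 0.437 with an estimated correlation). Ldha, lactate dehydrogenase A, had -1.06 (SE 0.35), Aldoa -0.45, Pgk1 -0.37 and Pgam1 -0.22, none past the threshold alone. Ribosomal protein genes shifted downward as well, with 21 of 67 positive and a median of -0.10 (adjusted p = 0.0328, and adjusted p = 0.505 with an estimated correlation), Rpl17 (-0.90), Rps26 (-0.46), Rpl27a (-0.38) and Rpl7l1 (-0.59) having the smallest p. Without intermittent hypoxia 4 weeks A the ribosomal median was -0.03 (adjusted p = 0.306) and the glycolysis list had an adjusted p of 0.16. On the values as deposited the ribosomal list had an adjusted p of 0.053, and with the probe-number trend removed neither list passed (median -0.10 and adjusted p = 0.292 for glycolysis, median -0.09 and adjusted p = 0.0577 for ribosomal proteins). By limma 0 features passed, with 153 at an unadjusted p under 0.05, and 0 by the unmoderated test with adjustment. The smallest p values were those of Rrp1b (0.94), Epb41l1 (1.20), Dynlrb1 (1.28), Nexn (-1.31), Avpi1 (-1.08) and the replication clamp gene Pcna (-1.06). No member of either list passed when adjusted over the list alone.

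The change from 1 to 4 weeks itself differed between intermittent hypoxia and normoxia for 3 lists of energy metabolism. Glycolysis differed by a median of -0.63 (1 of 7 genes positive, adjusted p = 0.00189), tricarboxylic acid cycle enzymes by -0.50 (4 of 18 positive, adjusted p = 0.00633) and fatty acid oxidation with peroxisomal genes by -0.29 (4 of 17 positive, adjusted p = 0.0253). With an estimated correlation the adjusted p values were 0.21, 0.247 and 0.247. Oxidative phosphorylation, the largest energy list, did not pass (15 of 44 positive, median -0.13, adjusted p = 0.355). Pgk1 had -1.43 (SE 0.33, adjusted p = 0.33), Ldha -1.38 (SE 0.49), Ldhb -0.91 and Aldoa -0.63. Cs had -1.14, Pdhb -0.84, Dld -0.87 and Sucla2 -0.60, whose 2 probes gave 0.15 and -1.18. Among fatty acid genes, Acat1 had -1.66 (SE 0.74), the medium-chain acyl-CoA dehydrogenase gene Acadm -0.83, the peroxisome proliferation gene Pex11a -0.86 and Hadh -1.15. No member of these lists passed among all features, and 2 glycolytic genes passed with negative differences when adjusted over the list alone. By limma 0 features passed, with 480 at an unadjusted p under 0.05, and 0 by the unmoderated test with adjustment. Efhd2 (1.49), Nabp1 (2.19), Dsc2 (1.82), Nexn (-1.77), Pgk1 and the adenylate cyclase gene Adcy3 (-1.36) had the smallest p. Without normoxia 1 week A the tricarboxylic acid cycle list had a median of -0.28 (adjusted p = 0.107) and the fatty acid list an adjusted p of 0.124.

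**Figure D4:**
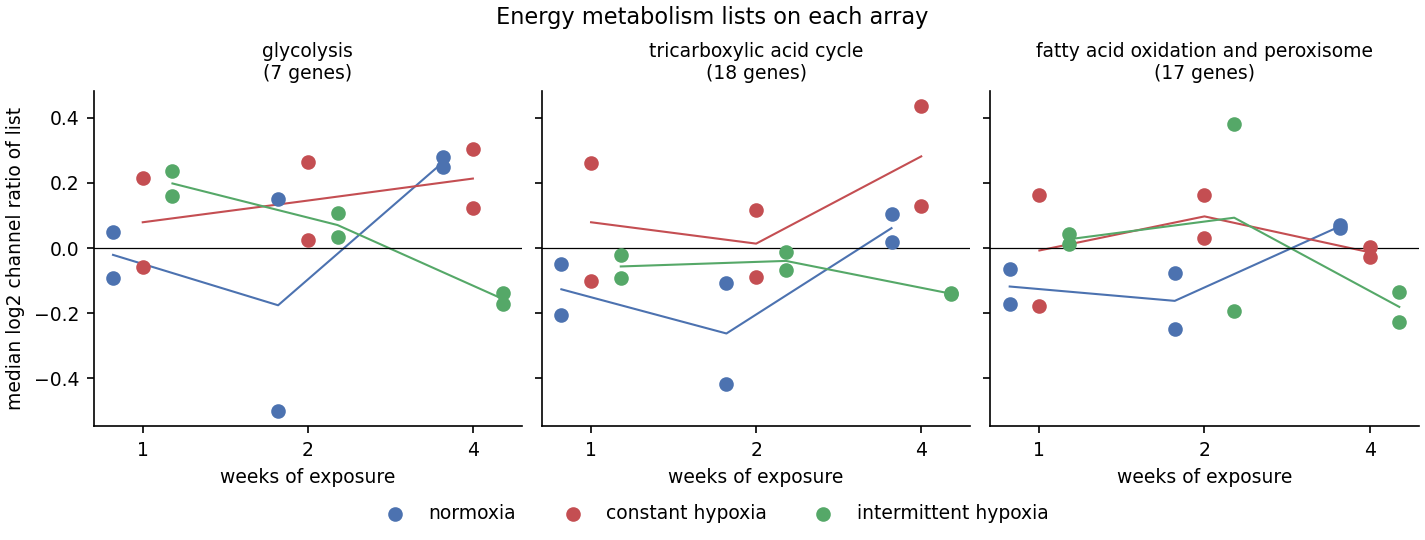
Median log2 channel ratio of the genes of 3 energy metabolism lists on each array (points) against weeks of exposure, with lines joining the mean of the 2 arrays of each group. The change from 1 to 4 weeks was upward in normoxia and downward in intermittent hypoxia, with median gene differences of 0.32 and -0.22 for glycolysis, 0.24 and -0.15 for the tricarboxylic acid cycle and 0.03 and -0.17 for fatty acid oxidation.

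The corresponding difference between constant hypoxia and normoxia passed for no list, the smallest adjusted p being 0.357. Fatty acid oxidation had 5 of 17 genes positive with a median of -0.35 (adjusted p = 0.67). By limma 0 features passed, with 200 at an unadjusted p under 0.05, 0 by the unmoderated test with adjustment and 1 on the values as deposited. Tapbp (1.44), Ppp4c (1.25) and the mitochondrial ribosomal protein gene Mrpl2 (1.10) had the positive differences of smallest p. Aldh3a2 (-2.34), Hdac2 (-2.76) and Ifitm3 (-2.47) had the negative ones. Aldh3a2 and Ifitm3 had a value on only 1 of the 4-week arrays of constant hypoxia. Without constant hypoxia 4 weeks B 503 features passed.

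The spread of ratios on an array was taken as the interquartile range over features. Because it runs over different features of 1 pair of animals, it does not measure how tightly any single transcript was controlled. It is informative only if the arrays had not been scaled to 1 spread, which is not known here. This spread ranged from 0.36 to 0.61 log2 units on the normoxia arrays, from 0.32 to 0.72 on the constant hypoxia arrays and from 0.31 to 0.88 on the intermittent hypoxia arrays. The mean ratio of these spreads was 0.98 for constant hypoxia against normoxia (two-sided exact permutation p = 0.87), 0.91 for intermittent hypoxia against normoxia (exact permutation p = 0.595) and 0.93 for intermittent against constant hypoxia (exact permutation p = 0.723), each with an adjusted p of 0.87 over the 3 tests and 924 assignments of 6 against 6 arrays. None of the 3 differences exceeded the spread between arrays.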

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

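All tests of explanations in this part were chosen after the results had been seen, and for the relation of the energy metabolism lists to Eif2s3y the expected outcome was written before it was computed.

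On constant hypoxia 4 weeks A, 16.39% of features lay beyond 2-fold, against 0.12% to 2.64% on the other 5 arrays of that condition. On intermittent hypoxia 2 weeks B, 13.67% lay beyond 2-fold, against 0.3% to 1.02% on its other 5 arrays, and its interquartile range was 0.88 against 0.31 to 0.46. The mean of the HIF targets on normoxia 2 weeks B was -0.34, against -0.03 to 0.13 on the other normoxia arrays. The mean of the erythroid markers on constant hypoxia 4 weeks A was -1.67, against -0.50 to 0.16 on the others. Among 39 sets of 6 arrays examined for a single array far from the rest, 5 gave one, where chance gives about 5% of sets.

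The sign of the sex-linked ratios changed between arrays that the labels describe alike. Noise of single spots does not predict that Eif2s3y and the Xist and Tsix probe oppose each other, and they did on 9 of 10 arrays. However, the chosen probes of Sfpq, Kif1b and Nfix followed the latter, and a probe of Xist alone stayed between -0.41 and 0.33. Probes near that of Eif2s3y were not examined. A deposited ratio with its sign turned on some arrays would give negative correlations with the remaining arrays, and the lowest was 0.10, although 11 of 153 single pairs of arrays correlated below 0. Animals whose sex differed from the label on some arrays remain a candidate explanation. At 4 weeks, when androgen-dependent genes can separate the sexes, their mean followed Eif2s3y with r = 0.98. However, Gusb among them kept a positive sign (0.77 on intermittent hypoxia B). The female-biased gene Slc22a7 did not run against Eif2s3y either (0.69 on normoxia B and -0.31 on intermittent hypoxia B). Kdm5c, negative on all 18 arrays and with r = -0.16 to Eif2s3y, gave this reading no support, while the mean of 3 such X-linked genes had r = -0.51 (permutation p = 0.0288, adjusted p = 0.115), and a constant dye effect on Kdm5c was not tested, so the sexes of the animals stay open.

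The mean ratio differed from 0 for 1050 features under constant hypoxia. A trend along the probe numbers may account for part of them: 561 features passed with block medians removed and 2 with a running median removed, their median size in the latter falling from 0.52 to 0.11 while the median standard error fell by less, from 0.13 to 0.08. Removing such a trend also takes out any biology shared by neighbouring probes. A dye bias common to all arrays and a difference between the paired animals cannot be told apart without swapped dyes: both give a positive correlation between conditions, which was 0.66 for normoxia and constant hypoxia. The trend along the probe numbers was still in these values, and a trend shared by arrays would give such a correlation too. An effect of constant hypoxia on the ratio stays open, since no feature passed in constant hypoxia minus normoxia on centred values. Such an effect also cannot be told apart from the other footing on which the constant hypoxia values were deposited.

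The change from 1 to 4 weeks differed between intermittent hypoxia and normoxia for glycolysis (-0.63, from 0.32 in normoxia and -0.22 in intermittent hypoxia), the tricarboxylic acid cycle (-0.50, from 0.24 and -0.15) and fatty acid oxidation (-0.29, from 0.03 and -0.17). A part of the probe-number trend in this cannot be told apart. All 3 lists passed after its removal, as did 8 of 16 lists in this contrast. The medians of glycolysis and fatty acid oxidation moved to -0.31 and -0.15, and that of the tricarboxylic acid cycle to -0.59. None of the 3 passed with the estimated correlation (adjusted p = 0.278, 0.389 and, for the tricarboxylic acid cycle, 0.313). Members that vary together between arrays of a group may make the preset test too generous: with the estimated correlation the smallest adjusted p was 0.21, so the shift is not shown to exceed the spread between arrays. Mixed sexes of the paired animals cannot be told apart from an effect of oxygen: over 18 arrays the mean of the 3 lists followed Eif2s3y with r = 0.17 (permutation p = 0.515), and over the 4-week arrays with r = 0.79 (exact permutation p = 0.0431, adjusted p = 0.115, r = 0.45 without the 2 farthest arrays). By the bound set beforehand the values over 18 arrays would argue against mixed sexes, but that bound was too wide. The mean of the androgen-dependent genes was seen to follow Eif2s3y at 4 weeks, and the younger arrays dilute the test.

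Assignments of the arrays to conditions within each duration, the real one and others drawn at random, numbered 100 out of 108 possible. For constant hypoxia minus normoxia and intermittent hypoxia minus normoxia the real count of features was 0, which all 100 match by construction, so nothing was learned about chance there (at most 3 and 2 features in another assignment). The 1 list that passed in constant hypoxia minus normoxia was matched in 47 of 100 assignments, the real one included, with at most 5 lists in another, so chance cannot be excluded for it. The 2 features of intermittent minus constant hypoxia were matched in 3 of 100, the real one included, with 2 in the highest other. No correction was made for the other counts tested this way. The real assignment also separates arrays whose values were deposited on different footings, so this count cannot be assigned to oxygen. The Arrb2 call among them was lost in most fits that left out 1 array.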

How the results depend on the processing

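The alternatives that remove a trend along the probe numbers or leave out both wide-spread arrays were chosen after seeing the data, the others before. Counts below follow the main ones of 203, 1050 and 333 features for the ratios of normoxia, constant and intermittent hypoxia, 2 for intermittent minus constant hypoxia, 0 for the other comparisons and 8 for the list tests, leaving aside single durations and the 2-week steps in normoxia. Where no construction is named, the cause was not tested. As deposited, 5687 features passed for constant hypoxia, 5570 for constant hypoxia minus normoxia, 5386 for intermittent minus constant and 1 for the maturation difference of constant hypoxia, because the offset of those arrays was kept. The signs of Rap1b (-0.16), Adam19 (-0.31), Psmd1 (-0.25) and Slc22a7 (-0.43) in constant hypoxia, of Ptgr2 (-0.28), Sdhd (-0.21), Etv5 (-0.21), Aar2 (-0.35), Wdr43 (-0.33), Pdhb (-0.35) and Idh3b (-0.35) against normoxia, and of Slc44a2 (0.03), Etf1 (0.19), Dnajc2 (0.03) and Pdia6 (0.23) between regimes were reversed by it. With a running median of probe numbers removed, the 3 ratios gave 76, 2 and 101, maturation in intermittent hypoxia 1, its difference from normoxia 1 and the lists 24. Aldh3a2 was then reversed in constant hypoxia (0.12) and in its maturation (0.39, and 0.22 with block medians), and Hdac2 in the latter (0.05). With block medians removed, the 3 ratios gave 390, 561 and 703 and the lists 14. Without both wide-spread arrays, normoxia gave 725, constant hypoxia 683, constant hypoxia minus normoxia 1, intermittent minus constant 4, maturation in normoxia 7 and the maturation difference of intermittent hypoxia 1. Quantile normalization gave 460 for normoxia, 717 for intermittent hypoxia, 1 for constant hypoxia minus normoxia, 1 for intermittent minus constant, 1 for maturation in intermittent hypoxia, 1 for its difference from normoxia and 14 lists. Scaling to 1 median absolute deviation gave 585 for intermittent hypoxia, 1 for intermittent minus constant and 1 for maturation in intermittent hypoxia. Features complete on all 18 arrays, which are fewer, gave 71, 614 and 105 for the ratios, 0 for intermittent minus constant and 0 lists, and reversed Sucla2 (0.19) in the maturation difference of intermittent hypoxia. At least 1 value per group gave 1 for constant hypoxia minus normoxia, and single probes gave 15 lists. Only the arrays compared, a smaller fit, gave 0 for constant hypoxia, 103 for intermittent hypoxia, 0 for intermittent minus constant, 1 for maturation in normoxia and 13 lists. Array weights gave 132 for normoxia, 100 for intermittent hypoxia, 1 for intermittent minus constant, 4 for maturation in normoxia and 1 in intermittent hypoxia. Both arrays of a group received the same weight, such as 0.4 for constant hypoxia 4 weeks and 0.39 for intermittent hypoxia 2 weeks. These weights thus weighed groups and could not set an outlying array against its partner. An adjusted p under 0.10 gave 520, 1706 and 773 for the ratios. The unmoderated test with adjustment gave 520 for constant hypoxia and 0 for intermittent minus constant. At 1.5-fold with an unadjusted p under 0.05 it gave 74, 452 and 106 for the ratios, 67 for constant hypoxia minus normoxia, 21 for intermittent hypoxia minus normoxia, 101 for intermittent minus constant, 321, 303 and 91 for maturation in normoxia, constant and intermittent hypoxia, and 146 and 421 for the maturation differences of constant and intermittent hypoxia. The additive model gave 0 for intermittent minus constant. The estimated correlation and fry gave 0 lists. With the array letter as a replicate block, intermittent minus constant gave 0 and the ratios 161, 1000 and 260. Letters shared only a name: over 36 pairs of groups same-lettered deviations correlated at a median of 0.01 (-0.37 to 0.44), 8 of them over 0.1. Robust moderation gave 202, 1039 and 328 for the ratios and left the other feature counts unchanged. Leaving out single arrays, where the lone array left is assumed to vary like the other groups, gave 13 (without normoxia 4 weeks B) to 453 (without either constant hypoxia 4 weeks array) for normoxia, 6 (without constant hypoxia 1 week B) to 1365 for constant hypoxia and 43 (without intermittent hypoxia 1 week B) to 899 (without intermittent hypoxia 2 weeks A) for intermittent hypoxia. It gave 0 to 567 for constant hypoxia minus normoxia, 0 to 672 for intermittent minus constant, 0 to 752 for maturation in constant hypoxia and 0 to 503 for its difference from normoxia, each highest without constant hypoxia 4 weeks B. It gave 0 to 1 for intermittent hypoxia minus normoxia, maturation in normoxia, maturation in intermittent hypoxia and its difference from normoxia, and 4 (without normoxia 1 week A) to 19 (without normoxia 4 weeks A) lists. The spread tests stayed on the same side of the threshold with every measure of spread, filter and array left out that was run. Signal over background is not known here, so its effect on single values was not assessed.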

Other observations

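Hdc, the enzyme that makes histamine, had the largest difference at a single duration among the named genes, and was singled out after its values had been seen. At 2 weeks it stood at 3.01 and 2.83 on the normoxia arrays, at -4.0 and -1.52 on the constant hypoxia arrays and at -1.91 on intermittent hypoxia A. At 4 weeks its ratio was -0.62 on normoxia A, -0.37 and -0.13 on constant hypoxia A and B, and -0.55 and 0.94 on intermittent hypoxia A and B. On intermittent hypoxia 1 week B it was -1.80. A second Hdc probe, which missed the filter, gave 1.79 on normoxia 2 weeks A and -1.90 and -0.44 on constant hypoxia 2 weeks A and B, and -1.75 on normoxia 4 weeks B, where the first probe had no value. Hdc had the opposite sign to Eif2s3y on 10 of 16 arrays, among them normoxia 2 weeks A and constant hypoxia 2 weeks A (Eif2s3y -1.84 and 1.32), and the same sign on 6, among them the B arrays of both groups (0.42 and -0.64), so condition was not the only difference between these arrays.

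With the trend along the probe numbers removed, a setting chosen after seeing the data, translation factors and mitochondrial ribosomal proteins had 22 of 76 members positive in the change from 1 to 4 weeks of intermittent hypoxia against that of normoxia, with a median of -0.21 (adjusted p = 0.00414, and adjusted p = 0.00608 with an estimated correlation). The correlation estimated for this list was 0.009, below the preset 0.01, so the test with the estimated correlation was no stricter for it. Eif2s3y is a member of the list as fixed. Before removal the list had 32 of 77 positive, a median of -0.22 and an adjusted p of 0.073. In the same contrast, proteasome and ubiquitin genes had 12 of 48 positive after removal (median -0.21, adjusted p = 0.0104, and adjusted p = 0.209 with an estimated correlation).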
